A study of Mus musculus with 55 samples.

How the data were processed

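RNA sequencing counts of 26 mouse oocyte libraries were used, per the labels from ovary or oocytes: growing oocytes (3 control, 3 Dhx36 sko), the groups c, c_DRB, rhau_sko and rhau_sko_DRB (2 each), GV_C and GV_cPDS_12h (3 each), and Trim_control_3h and Trim21_3h (3 each). The values deposited by the authors are raw read counts per gene, with a column layout that featureCounts writes, per the file headers. The submitters' processing notes name fastp 0.21.0, cutadapt 1.15, HISAT2 2.1.0, STAR 2.5.2b and featureCounts 2.0.1 beside Bowtie2 2.5.1, MACS3 3.0.0b3, deepTools 3.5.4, ChIPseeker, bedtools, DESeq2 and HOMER for the series as a whole. The notes name mouse build mm9 and do not say which tool made which table. The order and settings of those steps, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. Genes that overlap on opposite strands and members of multigene families were therefore read as uncertain.

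One table held 20 libraries and 33924 genes by symbol, the other 6 libraries (Trim) and 37310 features by versioned Ensembl identifier. Of the latter, 33581 were given the symbol of the gene with identical exons in the first table and 2844 the symbol in a reference table of names, and 885 stayed unnamed. In the first table, 25 symbols that had been turned into dates were restored, and 99 features on more than 1 chromosome were kept. A further table repeated the first (26 columns compared, 0 cells different) and was not used. Every sample column was mapped to a label (0 unmapped). The other assays of the series were not analysed here.

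Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10), library sizes were scaled with TMM factors, and a quasi-likelihood test gave p-values that were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are printed with standard errors (SE) taken as the absolute log2 fold change over the square root of the test's F. This SE can be too small for large changes where a group has few counts. Log2 CPM used a prior count of 2. Normalised CPM are taken on the TMM-scaled library size and given as mean ± SD. The growing, cPDS and Trim comparisons were fitted on their own 6 libraries each. The DRB experiment was fitted as 1 model of 8 libraries with 1 term per group, since 2 libraries per group leave few degrees of freedom, and the interaction was the DRB change in sko minus the DRB change in c. Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The fits of the 6 deep libraries of the DRB experiment, and the test of the sko change between experiments on 12 libraries, were chosen after seeing the data.

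The named genes were chosen by rule. For each comparison they are the 6 genes with the largest increase and the 6 with the largest decrease among called genes with a mean log2 CPM of at least 4, no overlap between the groups' libraries and an informative symbol (4 each way for the interaction, sko with DRB and DRB in sko). Where fewer than 10 genes passed, the 5 with the smallest p each way were taken, called or not. These too were drawn from genes of that abundance with an informative symbol. Added to these were the 2 called members with the smallest p in each gene list, and Dhx36, Trim21, Cdk9, Hexim1, Zp3 and Gdf9 in every comparison. Where a comparison names many, the text gives a part of them with values and the rest as counts.

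The 23 gene lists were zona pellucida and oocyte-secreted factors, maternal effect genes, oocyte transcription factors, meiotic maturation, mRNA decay, P-TEFb and elongation, DNA damage response, R-loop processing, p53 targets, G-quadruplex helicases and binding proteins, immediate early genes, heat shock and stress response, interferon response, DNA methylation and chromatin regulators, zygotic genome activation, replication-dependent histones, ribosomal proteins, mitochondrial genome, nuclear oxidative phosphorylation, translation initiation factors, and markers of granulosa and cumulus, of theca and stroma, and of immune, endothelial and blood cells. They were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison with at least 5 tested members. The estimated setting also refers each test to the few residual degrees of freedom of the fit, not to the number of genes. A list that fails under it is therefore no check of the correlation alone. Counts of called members are given over all genes and adjusted over the list alone. The list of translation initiation factors was taken by symbol. It therefore also holds genes that do not encode initiation factors, such as Eif2ak3, Eif2c2 and Eif4ebp1.

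Fold changes of pairs of comparisons without a shared library were correlated across genes, and overlaps of calls were set against the number expected of independent lists. For genes at 0 in a group, a floor of 3 counts over the group gives a lower bound, and for genes with 1 to 3 counts an exact 95% interval of the ratio is given. Intervals of Dhx36 levels are 95% Wilson intervals, and that of the share of Trim genes nearer to the controls is an exact binomial one. Total counts ran from 127927 to 65444652, and the depth of each library limits its precision as these intervals show. Tests were checked on simulated data drawn from the real means and library sizes, with 200 changed genes and a changed list of 40 others. Genes changed 2-fold were recovered in 93% of cases in growing oocytes, 100% for cPDS, 92% for Trim, 75% in the 6 deep libraries, 19% for sko without DRB and 3% for the interaction. Genes changed 4-fold were recovered in 100%, 100%, 99%, 99%, 88% and 66% of cases. False calls among unchanged genes numbered 16, 10, 12, 16, 55 and 65 in the same order.

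The alternatives were RLE factors, library size alone, no filter beyond 1 count, a stricter filter of 5 CPM, DESeq2 1.42.0, limma-voom, removal of mitochondrial genes (and of Trim21 in the Trim experiment) before library sizes, each library left out in turn, a replicate block for cPDS and Trim, and fits of the 4 libraries of a contrast alone. Added after seeing the data were fits without the 2 shallow libraries and of the 6 deep libraries. A test of G-quadruplex motifs in transcripts and corrections for GC content need a genome sequence, which was not used here.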

Results

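Gene-level read counts were available for 26 RNA sequencing libraries of mouse oocytes, among 55 samples of the series. The libraries came from 4 experiments. In growing oocytes, 3 control libraries stood against 3 labelled Dhx36 sko, an abbreviation that the labels do not expand. DHX36, also called RHAU, is a helicase that unwinds G-quadruplexes, 4-stranded structures of guanine-rich RNA or DNA. A second experiment crossed genotype (c or rhau_sko) with DRB, an inhibitor of the transcription elongation kinase CDK9, in 4 groups of 2 libraries each. Germinal vesicle (GV) stage oocytes gave 3 libraries labelled GV_C and 3 labelled GV_cPDS_12h, where cPDS (carboxypyridostatin) is a ligand that stabilises RNA G-quadruplexes and 12 h is the time on the label. The fourth experiment held 3 Trim21 libraries and 3 control libraries at 3 h. TRIM21 is a ubiquitin ligase that binds antibodies, and the Trim-Away method uses it to degrade the protein that a delivered antibody recognises. The column headers of that experiment name Dhx36. The other assays of the series were not analysed here.

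Total counts ran from 31930695 to 41075545 in the growing oocyte libraries, from 26509060 to 65444652 in the GV libraries and from 7452742 to 32704737 in the Trim libraries. In the DRB experiment, 6 libraries held 23010562 to 40968105 counts, whereas c_DRB replicate 4 held 129192 and the library labelled rhau_sko replicate 6 held 127927. These 2 shallow libraries also differed in content. Mitochondrial transcripts took 5.92% and 9.41% of their counts, against 0.126% to 0.633% in the 6 deep libraries of the same experiment. Casp8 was their most abundant gene at 1.69% and 2.58% of counts, while Spin1 led in each of the 6 deep libraries. Intervals and floors given here cover counting error only, since reads without molecular identifiers are not independent molecules. No spike-in is given in the sources used here, so every level is relative to the other transcripts of its library. Whether replicates are separate animals or repeated libraries of a pool is not stated.

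**Figure D1:**
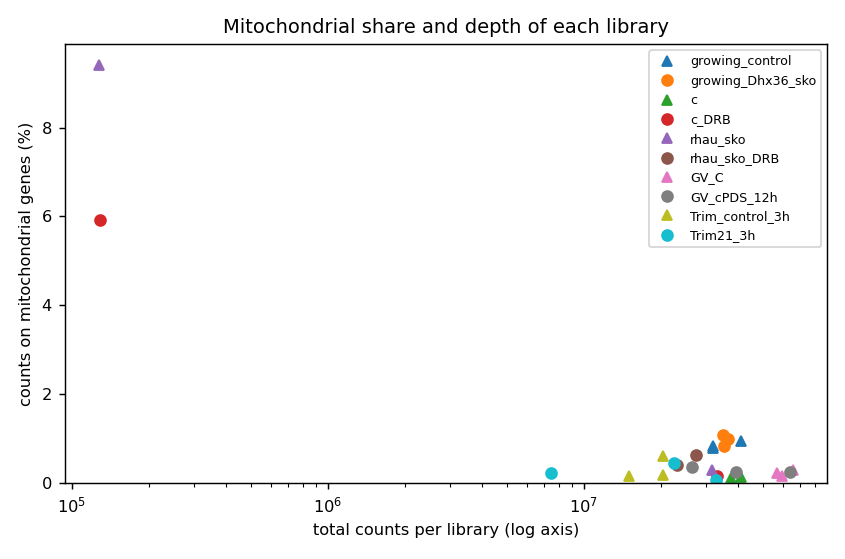
Percent of counts on mitochondrial genes (linear y axis) against total counts per library (log x axis), 1 point per library. The 2 shallow libraries of the DRB experiment sit at 5.92% and 9.41%, and the other 6 of that experiment at 0.126% to 0.633%.

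Dhx36 (mm9, chromosome 3, 62273961 to 62310926, minus strand) was measured in every library first, as the targeted gene. Growing control oocytes carried 8.29 ± 2.28 CPM (counts scaled to 1e6 per library; SD, n = 3) and growing sko oocytes 2.31 ± 0.620 CPM (SD, n = 3). In the DRB experiment the 2 c libraries read 46.9 and 42.2 CPM and c_DRB replicate 3 read 39.2 CPM. The sko libraries read 7.63 CPM (replicate 5, without DRB), 4.43 CPM and 5.68 CPM (with DRB). The library labelled rhau_sko replicate 6 went against its label with 46.9 CPM, which rests on 6 counts and has a 95% Wilson interval of 21.5 to 102 CPM. That interval lies above the 6.73 to 8.66 CPM of replicate 5 and includes both c libraries. The shallow c_DRB replicate 4 read 31.0 CPM from 4 counts, with an interval that reaches up to 79.6 CPM. Dhx36 was at 21.7 ± 1.23 CPM in GV_C and 35.1 ± 3.41 CPM in the cPDS libraries (SD, n = 3 each). The Trim21 libraries carried 7.74 ± 1.49 CPM of Dhx36 against 30.4 ± 0.676 CPM in their controls (SD, n = 3 each). Trim21 itself reached 8461 ± 791 CPM in the Trim21 libraries and 14.7 ± 0.288 CPM in their controls, and no other library exceeded 0.361 CPM.

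**Figure D2:**
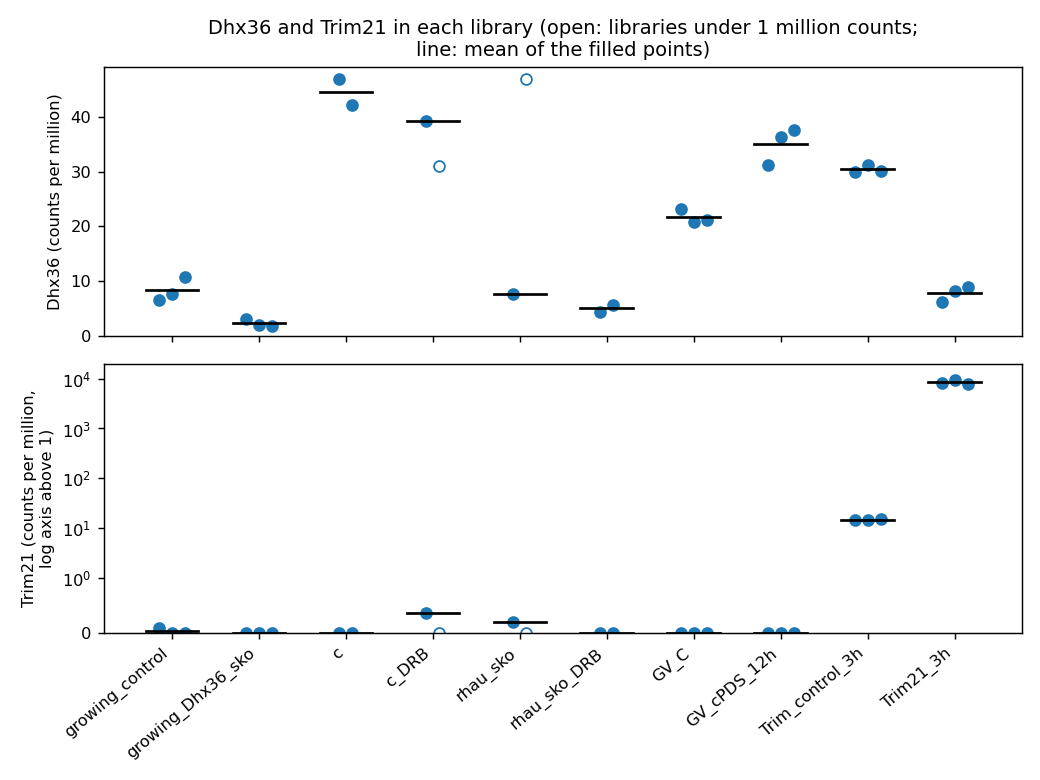
Dhx36 (top, CPM) and Trim21 (bottom, CPM on a log axis above 1) in each of the 26 libraries by group. Open points are the 2 shallow libraries and lines are means of the filled points. Dhx36 averages 8.29 CPM in growing control and 2.31 CPM in growing sko libraries, and Trim21 reaches 8461 CPM in the Trim21 libraries.

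The growing oocyte comparison asks how transcript levels differ where Dhx36 is lower. Mt1, which encodes a metal-binding metallothionein (chromosome 8, 96702989 to 96704225), rose from 0.0739 ± 0.101 to 98.2 ± 9.97 normalised CPM (SD, n = 3 each), a log2 fold change of 10.35 ± 0.33 (SE). With so few control counts, this SE can be too small. Fshr, the receptor for follicle-stimulating hormone (chromosome 17, 89384292 to 89600015), rose from 0.342 ± 0.0880 to 37.0 ± 1.72 CPM. Ebf1, a lymphoid transcription factor gene, rose from 0.202 ± 0.0614 to 34.7 ± 10.8 CPM, and Plac1, best known from the placenta, rose 58.9-fold to 226 ± 55.7 CPM. The alpha-tubulin gene Tuba3b fell from 57.6 ± 19.7 to 0.752 ± 0.274 CPM, a value left uncertain by other tubulin copies. Dhx36 fell by 2.01 on the log2 scale (SE 0.24; edgeR adjusted p = 4.24e-06) and was lower in 3 of 3 sko libraries than in any control.

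Krt71, a hair follicle keratin gene, changed by 5.70 ± 0.22 (log2 fold change ± SE here and for the genes that follow) and Ndufa4l2, a relative of a respiratory chain subunit gene, by 5.61 ± 0.22. On the other side, Fam84b changed by -3.91 ± 0.20, the X-linked multicopy gene Xlr3b by -2.83 ± 0.19 and Znfx1, an RNA helicase gene, by -2.78 ± 0.19. Cdc42ep3, an effector gene of the CDC42 GTPase, changed by -2.72 ± 0.24 and the keratin gene Krt12 by -2.65 ± 0.18. Xlr3b has near-identical copies, so its value is uncertain. Each of these 7 genes had groups of 3 libraries that did not overlap. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7566 of 14081 tested genes (53.7%). Of these, 4017 were higher and 3549 lower in sko oocytes, and 2620 and 1278 changed at least 2-fold. With library size alone in place of TMM factors, 4823 were higher and 2386 lower (66.9% higher, against 53.1%), and the median of all genes moved from 0.02 to 0.21 on the log2 scale.

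Several transcripts that oocytes store for growth and maturation were lower in growing sko oocytes. Folr4, which encodes the egg receptor for sperm IZUMO1, fell by 2.35 (SE 0.14), Fgf8, an oocyte growth factor gene, by 1.14 (SE 0.13) and Zar1, a maternal effect gene, by 1.95 (SE 0.14). Mos, a kinase gene of meiotic arrest, changed by -1.40 ± 0.12 and the spindle checkpoint gene Bub1b by -1.84 ± 0.16. Zp3, a glycoprotein gene of the egg coat, fell from 9116 ± 931 to 6099 ± 411 CPM (log2 fold change -0.58 ± 0.13; edgeR adjusted p = 0.00147; lower in 3 of 3 libraries). Gdf9, another oocyte growth factor gene, did not pass at 0.06 ± 0.13 (edgeR adjusted p = 0.692), but did with library size alone (0.26, adjusted p = 0.0384; 0.0384 to 0.990 over all alternatives). Among 12 tested members of the list of zona and oocyte-secreted factors, 6 were lower and the other 6 not called, against 3 higher and 5 lower with library size alone. The maternal effect list had 1 higher and 9 lower of 21, or 3 and 8 with library size alone. Meiotic maturation genes had 5 higher and 12 lower of 33, a balance that became 9 and 10 with library size alone, where their median turned from -0.13 to 0.07. None of these 3 lists passed camera (adjusted p = 0.0607, 0.0607 and 0.148, or 0.621, 0.569 and 0.621 with an estimated correlation).

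Genes of transcription and RNA metabolism moved both ways. Ccnt1, which encodes the cyclin T1 partner of CDK9, rose 4.40-fold to 52.8 ± 2.77 CPM (SD, n = 3), and Cdk9 changed by 2.35 ± 0.43 at 0.440 to 2.30 CPM (edgeR adjusted p = 2.73e-04; higher in 3 of 3). Ddx6, a helicase gene of mRNA storage and decay, rose 4.40-fold to 63.6 ± 8.73 CPM, while Pabpn1l, an oocyte poly(A)-binding protein gene, changed by -1.61 ± 0.17. Obox3, a member of a multicopy homeobox family and so uncertain, changed by 4.73 ± 0.24, and Sohlh2, a factor of early oocytes, by 1.93 ± 0.16. The p53 target genes Btg2 and Mdm2 rose by 2.39 ± 0.17 and 1.90 ± 0.16, and the histone demethylase genes Kdm5b and Kdm1b by 2.27 ± 0.17 and 1.88 ± 0.16. Atrx, a chromatin remodeller gene, changed by -1.18 ± 0.11 and Ddx5, an RNA helicase gene, by 1.02 ± 0.12. Hexim1, an inhibitor gene of CDK9, had 22 counts over the 3 sko libraries and 2 over the 3 controls, a ratio of 10.8 (95% counting interval 2.66 to 94.8).

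The gene lists put these single genes in context, and counts adjusted over the list alone were the same as those over all genes unless given. Ribosomal protein genes had 5 higher and 37 lower of 80 (5 and 40 adjusted over the list alone; 6 and 24 with library size alone), with Rpl17 at -1.18 ± 0.12 and Rps9 at -1.15 ± 0.13. This was the 1 list of 23 that passed camera with the preset correlation (adjusted p = 4.65e-04), and its adjusted p = 0.713 with an estimated correlation. Nuclear oxidative phosphorylation genes had 6 higher and 26 lower of 81 (6 and 25 adjusted over the list alone), or 7 and 15 with library size alone, where the median turned from -0.16 to 0.02. Translation initiation factors had 9 higher and 23 lower of 55 (9 and 25 adjusted over the list alone), but 13 and 12 with library size alone. DNA damage response genes had 7 higher and 22 lower of 40 (8 and 23 adjusted over the list alone), or 9 and 10 with library size alone. The mitochondrial genome list had 1 higher and 5 lower of 13, which became 2 and 2 with library size alone, and replication-dependent histones had 2 lower of 18. Hist1h1c, of these 2, lost its call without sko replicate 5 (-0.84, edgeR adjusted p = 0.0510; 0.00133 to 0.0510 over all alternatives), and Dub1a of the zygotic activation list without sko replicate 4 (1.18, edgeR adjusted p = 0.0804; 0.00642 to 0.0804 over all alternatives).

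Oocyte transcription factors had 8 higher and 5 lower of 19, p53 targets 7 and 3 of 20, heat shock and stress genes 7 and 5 of 18, and immediate early genes 7 and 5 of 19 (7 and 6 adjusted over the list alone). Interferon response genes had 4 higher and 1 lower of 7, and zygotic genome activation genes 4 higher of 6 with the other 2 not called. The P-TEFb and elongation list had 10 higher and 11 lower of 36 (10 and 12 adjusted over the list alone), which turned to 13 and 7 with library size alone. Its mean of 0.14 had the opposite sign to its median of -0.05 and to its camera direction. mRNA decay genes had 6 higher and 11 lower of 37 (median -0.19), or 8 and 7 with library size alone. The G-quadruplex helicase and binding protein list had 9 higher and 10 lower of 35, or 13 and 7 with library size alone, with a median of 0.08, a mean of -0.03 and a downward camera direction. R-loop genes had 5 and 5 of 24 (10 and 3 with library size alone; median -0.01 against an upward camera direction), and chromatin regulators 7 and 13 of 27 (median -0.36), or 8 and 8 with library size alone.

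Markers of cells that surround the oocyte were counted as a background. Granulosa and cumulus markers had 7 higher of 13 (7 higher and 1 lower adjusted over the list alone), led by Fshr, and Cyp19a1, the aromatase gene, changed by 1.11 ± 0.17. These markers took 0.0873% to 0.0993% of counts in the 3 controls and 0.135% to 0.148% in the 3 sko libraries. Theca and stroma markers had 3 higher and 1 lower of 5. Immune, endothelial and blood markers had 2 higher and 2 lower of 6, with a median of -0.26 but a mean of 1.16 and an upward camera direction. The leukocyte gene Ptprc had no count in the 3 control libraries and was at least 56.0-fold higher in sko oocytes, against a floor of 3 counts over the group, and Mx2, an interferon-induced gene, was at least 13.8-fold higher on the same floor.

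In the DRB experiment, the comparison of rhau_sko with c asks the same question in other libraries, here without and with DRB. Mt1 was higher in sko without DRB by 6.52 ± 0.46 and with DRB by 6.81 ± 0.54 (log2 fold change ± SE, n = 2 per group). Ddx6 was higher by 3.03 ± 0.33 and 4.04 ± 0.40, and Dhx36 lower at -2.32 ± 0.46 (edgeR adjusted p = 0.00749) and -2.87 ± 0.39 (edgeR adjusted p = 0.00137). These directions hold the library labelled rhau_sko replicate 6 as sko, although its Dhx36 level went against that label. Without DRB, edgeR called 1134 genes higher and 572 lower of 16749, and with DRB 1126 higher and 598 lower. On simulated data the test without DRB made 55 false calls and recovered 19% of genes changed 2-fold and 88% of those changed 4-fold. More of the simulated calls were thus false than the threshold of 0.05 allows. Far fewer genes were changed in the simulation than were called in the real data. The false share of the real calls is therefore not known. The test with DRB was not simulated. The mitochondrial genes mt-Nd5 (7.93 ± 2.18) and mt-Nd6 (7.66 ± 2.05) and Casp8 (6.63 ± 1.90) were among the largest increases without DRB and were abundant in the shallow library of that group. None of these 3 was called without that library, where they changed by 1.10, 1.31 and 0.50 (edgeR adjusted p = 0.648, 0.560 and 0.837), nor, with folds about as large as with all libraries, without c replicate 1 (7.83, 7.60 and 6.60; adjusted p = 0.144, 0.136 and 0.161) or c replicate 2 (8.04, 7.74 and 6.66; adjusted p = 0.140, 0.132 and 0.158). The call of Dhx36 without DRB was lost with DESeq2 (-1.31, adjusted p = 0.669) and without c replicate 1 (-2.04, edgeR adjusted p = 0.149), c replicate 2 (-2.21, 0.124) or rhau_sko replicate 5 (-0.16, 0.934), and that of Ddx6 without rhau_sko replicate 5 (2.22, 0.0549). Over all alternatives the adjusted p of Dhx36 ran there from 2.40e-06 to 0.934. With DRB, Mt1, Ddx6 and Dhx36 were not called without c_DRB replicate 3, at 17.26, 5.87 and -2.38. That fit leaves the shallow library alone for c_DRB. Its median over all genes was 5.13, against 0.06 with all libraries, so its folds are not comparable with the others. The count without DRB dropped to 186 without c replicate 1, 132 without c replicate 2 and 104 without rhau_sko replicate 5. With DRB it was 1108 without rhau_sko_DRB replicate 7 and 0 without c_DRB replicate 3 (edgeR, 2156 genes at unadjusted p under 0.05).

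A fit of the 6 deep libraries, 3 of each genotype, with DRB as a covariate was chosen after the depths had been seen. DRB was unbalanced in it, with c_DRB replicate 3 among the controls and rhau_sko_DRB replicates 7 and 8 among the sko libraries. CPM means and shares of counts of these libraries, here and below, were adjusted for neither DRB nor genotype. Mt1 rose from 7.03 ± 1.07 to 854 ± 24.6 CPM (SD, n = 3 each), Ddx6 from 27.4 ± 2.54 to 354 ± 74.3 CPM and Fshr from 1.34 ± 1.22 to 23.5 ± 7.69 CPM. Zfpm2, a cofactor gene of GATA factors, rose 69.8-fold and Serpinb1a, a protease inhibitor gene, 39.8-fold, and Ebf1, Plac1 and Tceal8 changed by 6.74 ± 0.35, 4.77 ± 0.27 and 4.48 ± 0.42 (log2 fold change ± SE). Galntl5, a testis-type glycosyltransferase gene, fell by 3.37 (SE 0.25), the phosphatase gene Ubash3b by 3.16 (SE 0.15), the glutathione peroxidase gene Gpx6 by 3.15 (SE 0.20), the progranulin gene Grn by 2.62 (SE 0.19) and Nfil3 by 2.44 (SE 0.15). Dhx36 fell by 2.72 (SE 0.17; edgeR adjusted p = 2.40e-06; lower in 3 of 3). edgeR called 6020 of 15923 genes, 3163 higher and 2857 lower, with 1875 and 1140 changed at least 2-fold. Leaving out further libraries was not run on this fit.

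Zona and maternal effect transcripts were mostly lower in this fit. Of 12 zona and oocyte-secreted genes, 10 were lower (11 adjusted over the list alone), among them Zp3, from 2680 ± 203 to 1272 ± 109 CPM, and Astl, the egg protease gene that acts on the zona, at -1.61 ± 0.13. Gdf9 changed by -0.60 ± 0.14 (edgeR adjusted p = 0.00609; lower in 3 of 3). The maternal effect list had 1 higher and 13 lower of 21 (1 and 15 adjusted over the list alone), including Bnc1 at -1.17 ± 0.13, whereas oocyte transcription factors had 5 higher and 3 lower of 19. Granulosa and cumulus markers had 4 higher of 15 and none lower, with a median of -0.30, and took 0.0812% to 0.0956% of counts in the 3 sko libraries against 0.0714% to 0.0788% in the 3 controls. Ribosomal protein genes had 3 higher and 21 lower of 82 (3 and 19 adjusted over the list alone), and the mitochondrial genome list 9 higher of 10, with mt-Nd1 at 1.87 ± 0.23. Genes without a count in 12 growing and GV libraries were higher in the same sko libraries, at 31.3, 34.2 and 45.8 CPM in sum against 19.8 to 20.3 CPM in the controls. The zona, maternal effect, ribosomal protein and mitochondrial genome lists passed camera with the preset correlation (adjusted p = 1.95e-05, 7.98e-05, 0.00439 and 3.63e-05), whereas with an estimated correlation their adjusted p = 0.725, 0.725, 0.754 and 0.738. In the 8-library fit the zona list also passed without DRB (adjusted p = 1.49e-04; 0.799 with an estimated correlation) and with DRB (adjusted p = 4.17e-09; 0.392 with an estimated correlation). The G-quadruplex list had 14 higher and 3 lower of 35 (15 and 4 adjusted over the list alone), with the helicase gene Wrn at 1.00 ± 0.12, and did not pass camera (adjusted p = 0.0734).

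Fold changes of the 6 deep libraries and of growing oocytes shared no library and were set side by side across 13684 genes. Pearson's r across genes was 0.71 and Spearman's rho 0.66, with the caution that genes are not independent replicates. Of the genes called in both, 1955 were higher in both (790 expected of independent lists) and 1806 lower in both (700 expected), while 89 and 102 went opposite ways. For the 8-library comparison without DRB, r with growing oocytes was 0.60 and with the comparison under DRB 0.52.

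**Figure D3:**
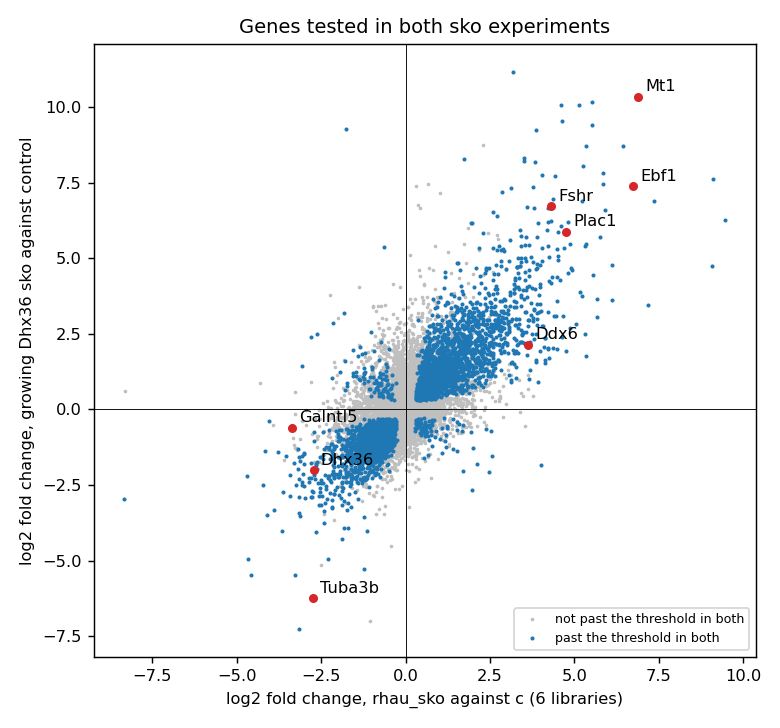
Log2 fold change of sko against control in the 6 deep libraries of the DRB experiment (x) and in growing oocytes (y), 1 point per gene tested in both. Mt1, Ebf1, Fshr and Plac1 lie high on both axes, and Dhx36 lies at -2.72 and -2.01.

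The DRB comparisons ask which transcripts depend on continued elongation, and whether that dependence differs by genotype. Herpud1, a gene of the endoplasmic reticulum stress response (chromosome 8, 96910338 to 96919277), was lower with DRB in c at -3.95 ± 0.52 (edgeR adjusted p = 0.0214) and in sko at -3.15 ± 0.41 (edgeR adjusted p = 0.0215). The 6 deep libraries, with genotype as a covariate, gave 47.6 ± 8.87 CPM without and 4.66 ± 2.58 CPM with DRB (SD, n = 3 each; log2 fold change -3.57 ± 0.30, edgeR adjusted p = 0.00237). Its call in c was lost with no filter beyond 1 count (-3.96, edgeR adjusted p = 0.0501). It was also lost with any 1 library of the contrast left out, which leaves 1 library in a group. The log2 fold change was then -3.71 without c replicate 1, -4.20 without c replicate 2 and -3.93 without c_DRB replicate 4. Without c_DRB replicate 3 it was -13.01, but the shallow library then stood alone for c_DRB. The median of all genes was -4.10 in that fit, so -13.01 does not measure a larger fold. Over all alternatives the adjusted p ran from 6.40e-27 to 0.549. Its call in sko was lost without rhau_sko replicate 5 (-2.28, adjusted p = 0.499), with DESeq2 (-3.02, 0.163) and with no filter beyond 1 count (-3.17, 0.0707), with a range of 9.64e-10 to 0.499. Dub1a, of a multicopy family and uncertain, was lower in sko at -4.91 ± 0.66 (adjusted p of 3.53e-21 to 1 over all alternatives). Without rhau_sko_DRB replicate 8 it was not called at -4.80. Its sign turned without rhau_sko replicate 5 (8.40), which leaves the library labelled rhau_sko replicate 6 alone in its group. The median of all genes was 3.62 in that fit, so the turn cannot be told apart from a shift of all genes. Zscan4d, a gene of early embryonic genome activation with near-identical copies, did not pass in the deep fit at -1.77 ± 0.24 (edgeR adjusted p = 0.0590).

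Few genes were called with DRB in the model of 8 libraries, and more when the 4 libraries of a contrast were fitted alone, with 64 higher and 166 lower in c and 80 higher and 36 lower in sko. In c, the 8-library model had 2 genes higher and 2 lower of 16749 (743 at unadjusted p under 0.05), and besides Herpud1 these were Gm15859 (5.84), Slc7a14 (5.25) and 1700047I17Rik2 (-3.95), named after their values were seen. In sko, 1 was higher (Sdc4, 5.70, named likewise) and 2 were lower (1035 at unadjusted p under 0.05). Leaving out 1 library gave 1 call without c replicate 1 or c_DRB replicate 4 and 0 without c replicate 2 or c_DRB replicate 3 (edgeR, 659 and 1520 genes at unadjusted p under 0.05). For DRB in sko it gave 21 calls without rhau_sko_DRB replicate 7, 5 without rhau_sko_DRB replicate 8 or the library labelled rhau_sko replicate 6, and 0 without rhau_sko replicate 5 (edgeR, 2274 genes at unadjusted p under 0.05). In the 6 deep libraries 1 gene was higher (C730034F03Rik, 3.68, named likewise) and Herpud1 lower. Adjusted over the list alone, the deep fit gave 43 of 82 ribosomal protein genes and 40 of 82 oxidative phosphorylation genes higher with DRB, at medians of 0.35 and 0.33, although none of them passed over all genes. Both lists passed camera with the preset correlation (adjusted p = 6.78e-28 and 2.37e-21) and neither with an estimated correlation (adjusted p = 0.444 for each).

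For the interaction of DRB and genotype, edgeR called 0 of 16749 genes (937 at unadjusted p under 0.05), DESeq2 called 5 and limma-voom 3. Among the named genes, Nupr1, a stress response gene, had the smallest p of the positive terms at 7.82 ± 1.80 (edgeR adjusted p = 0.251). Casp8 (-12.27 ± 2.63) and mt-Nd5 (-13.44 ± 2.92) had the smallest of the negative ones (edgeR adjusted p = 0.233 for both). Without rhau_sko replicate 5 the count was 10, with Casp8 and mt-Nd5 called (adjusted p = 0.0413 for both). Without rhau_sko_DRB replicate 7 it was 9, with Nupr1 called (adjusted p = 0.0476), without the library labelled rhau_sko replicate 6 it was 3, and without rhau_sko_DRB replicate 8 it was 2. Without the 2 shallow libraries the terms of Casp8 and mt-Nd5 were -0.050 and 0.37, and over all alternatives their adjusted p ran from 0.0223 to 0.979 and 0.0223 to 0.962, and that of Nupr1 from 0.0231 to 1.00. On simulated data the interaction test recovered 3% of genes changed 2-fold and 66% of those changed 4-fold, with 65 false calls. A 2-fold difference was thus not detectable at this design, and in the simulation the adjusted p did not hold the threshold of 0.05.

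The cPDS comparison asks how transcripts differ in GV oocytes after 12 h with a ligand of RNA G-quadruplexes. Pabpn1l fell from 753 ± 67.0 to 37.6 ± 7.68 normalised CPM (SD, n = 3 each), a log2 fold change of -4.33 ± 0.13 (SE). H1foo, the oocyte linker histone gene, fell from 6644 ± 113 to 1424 ± 86.5 CPM, and Plat, the tissue plasminogen activator gene, from 3127 ± 419 to 581 ± 33.8 CPM. Dnajb1, a heat shock cochaperone gene, fell 11.7-fold and Hnrnpa1, an RNA-binding protein gene, 14.5-fold. Increases were smaller, with Dazl, a translational regulator gene, rising from 517 ± 7.81 to 1098 ± 83.3 CPM. Dhx36 rose by 0.73 ± 0.10 (edgeR adjusted p = 1.82e-05; higher in 3 of 3), Zp3 by 0.36 ± 0.06 and Gdf9 by 0.59 ± 0.10, while Cdk9 did not pass at 0.00 ± 0.22.

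The decreases of largest size were in Arpc3, an actin nucleation gene (-4.97 ± 0.28), Nudc, a dynein regulator gene (-4.95 ± 0.16), Nat14 (-4.54 ± 0.14), Ddost, a glycosylation gene (-4.38 ± 0.15), Pabpn1l and H2-Ke2 (-4.22 ± 0.12). On the other side stood Obox2 (1.76 ± 0.25, a multicopy gene and uncertain), Prr23a (1.42 ± 0.11), the T-box factor gene Tbx19 (1.34 ± 0.09), Clvs1 (1.28 ± 0.09), the sialomucin gene Cd164 (1.20 ± 0.07) and the splicing factor gene Srsf2 (1.19 ± 0.09). edgeR called 8191 of 16115 genes (50.8%), 3778 higher and 4413 lower. Of these, 258 higher and 2047 lower changed at least 2-fold. The labels give no culture time for GV_C, so the ligand and the time in culture could not be separated.

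Genes for proteins that bind or unwind G-quadruplexes fell as a list after cPDS, with 7 higher and 24 lower of 35 and a median of -0.55. Hnrnpa1 changed by -3.86 ± 0.11 and Ddx3x, an RNA helicase gene, by -1.30 ± 0.06, against a rise of Dhx36. The list passed camera with the preset correlation (adjusted p = 2.44e-04), and its adjusted p = 0.161 with an estimated correlation. Ribosomal protein genes had 38 higher and 13 lower of 82 (40 and 13 adjusted over the list alone; camera adjusted p = 0.00644, or 0.976 with an estimated correlation), while Rpl19 changed by -1.91 ± 0.08. p53 targets had 3 higher and 11 lower of 22, led by Bax, a cell death gene, at -4.42 ± 0.19. Granulosa and cumulus markers had 2 higher and 6 lower of 17, with a median of -0.41 (camera adjusted p = 0.658, or 0.976 with an estimated correlation), and took 0.0547% to 0.0595% of counts after cPDS against 0.0751% to 0.0776% in GV_C. Translation initiation factors had 15 higher and 24 lower of 56 (16 and 24 adjusted over the list alone), with Eif5a at -4.19 ± 0.12. Maternal effect genes had 9 higher and 9 lower of 21, and meiotic maturation genes 12 and 15 of 33. Oxidative phosphorylation genes had 31 higher and 25 lower of 82 (33 and 25 adjusted over the list alone), with a median of 0.17 and a mean of -0.09. The mitochondrial genome list had 2 higher of 13 (neither adjusted over the list alone), mt-Co2 and mt-Co3. Both lost their calls under several settings, mt-Co2 without GV_C replicate 2 or 3 or GV_cPDS_12h replicate 2 or 3 (adjusted p up to 0.117; 0.00342 to 0.117 over all alternatives), mt-Co3 with library size alone (0.78, adjusted p = 0.0511), limma-voom (0.72, 0.0567) or a replicate block (0.81, 0.0612) and without GV_C replicate 2 or 3 or GV_cPDS_12h replicate 2 (adjusted p up to 0.199; 0.0219 to 0.199 over all alternatives).

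In the Trim experiment the comparison asks what differs between the Trim21 and control libraries labelled 3 h. The column headers of both groups name Dhx36 and do not state its role. The counts measure transcripts, not the protein that Trim-Away degrades. Dhx36 transcripts fell by 1.99 (SE 0.18; edgeR adjusted p = 1.43e-05) and were lower in 3 of 3 Trim21 libraries than in any control. Trim21 rose by 9.17 ± 0.13. Tox3, an HMG-box gene, had 3261 counts over the Trim21 libraries and 2 over the controls, a ratio of 1452 (95% counting interval 402 to 11995). Entpd1, an ectonucleotidase gene, had no count in the Trim21 libraries and was at least 817-fold lower, against a floor of 3 counts over the group. Mei4, a gene of meiotic recombination, rose from 4.41 ± 0.227 to 155 ± 42.1 CPM (SD, n = 3 each) and Dbt, a mitochondrial enzyme gene, fell from 133 ± 18.9 to 5.41 ± 1.11 CPM.

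Besides these, Arid5b changed by 4.18 ± 0.27, Atpbd4 by 3.93 ± 0.12 and the spermatocyte gene Tex15 by 3.53 ± 0.26 (log2 fold change ± SE). Dcpp1 and Dcpp2, near-identical secreted protein genes and so uncertain, changed by -8.91 ± 0.30 and -6.48 ± 0.32, Spink2 by -5.14 ± 0.23 and the lipase gene Pnpla3 by -4.37 ± 0.95. edgeR called 1630 of 14191 genes, 888 higher and 742 lower, with 458 and 379 changed at least 2-fold. The count was 1043 without Trim21_3h replicate 1 and 928 without Trim21_3h replicate 3. Zp3 and Gdf9 did not pass at 0.13 ± 0.17 and 0.23 ± 0.17 (edgeR adjusted p = 0.704 and 0.446). Cdk9 did not pass at 0.98 ± 0.38 (adjusted p = 0.124), but did without Trim_control_3h replicate 1 (1.46, adjusted p = 0.0457; 0.0457 to 0.378 over all alternatives). Levels in 18 deep libraries of the other experiments were read for these genes. Tox3 lay there at 13.9 to 116 CPM, Mei4 at 106 to 306 CPM and Arid5b at 130 to 372 CPM, near the Trim21 libraries. Entpd1 lay at 13.1 to 43.8 CPM, near the Trim controls, and Dbt at 4.60 to 20.4 CPM, near the Trim21 libraries. Atpbd4 lay at 102 to 524 CPM, Tex15 at 21.3 to 356 CPM, Dcpp1 at no more than 0.191 CPM and Dcpp2 at a median of 1.21 CPM. Spink2 and Pnpla3 differed between the references, with Spink2 at 93.7 CPM in c and 1.98 CPM in GV_C (44.8 CPM in the Trim controls, 1.32 CPM with Trim21), and Pnpla3 at 513 CPM in growing controls and 4.04 CPM in GV_C (446 and 24.7 CPM in the Trim groups).

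**Figure D4:**
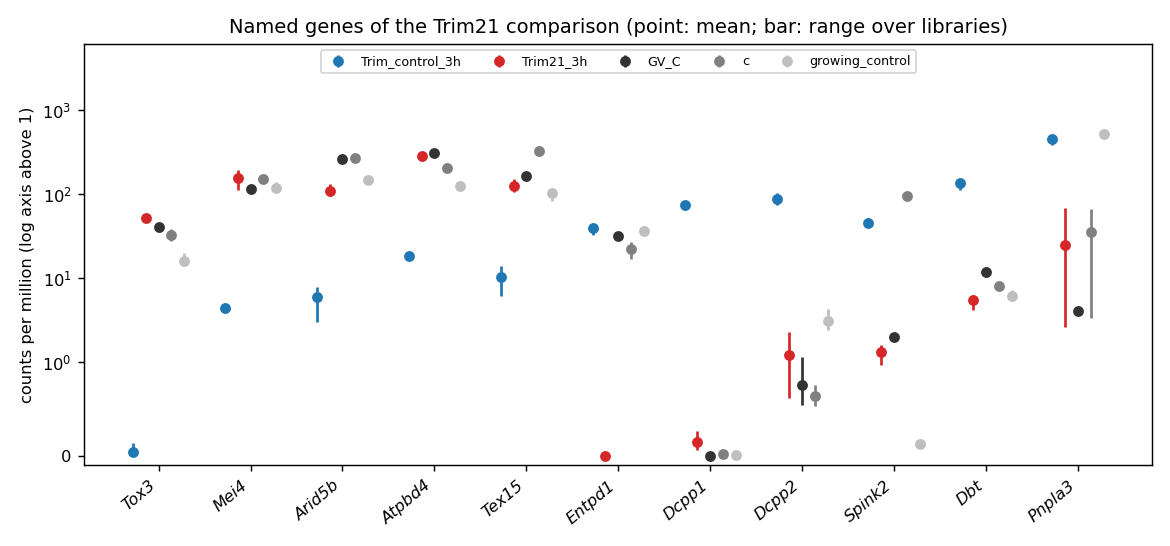
CPM (log axis above 1) of 11 genes with large differences between Trim21 and control libraries, in both Trim groups and in GV_C, c and growing_control; points are group means and bars the range over libraries. Tox3 averages 0.0444 CPM in the Trim controls and 52.1 CPM in the Trim21 libraries.

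Few list members were called in the Trim experiment. The maternal effect list had 2 higher and 1 lower of 21, oocyte transcription factors 1 and 1 of 16, and meiotic maturation genes 1 lower of 33. Ribosomal protein genes had 5 higher and 6 lower of 82 (5 and 10 adjusted over the list alone), with Rpl21 at 1.55 ± 0.16 and Rps2 at 1.29 ± 0.17, and oxidative phosphorylation genes had 5 lower of 82, with Cox6b1 at -0.68 ± 0.11. Both passed camera downward with the preset correlation (adjusted p = 8.79e-04 and 0.00556) and neither with an estimated correlation (adjusted p = 0.997 for each). Replication-dependent histones, a family of near-identical copies, had 3 higher and 4 lower of 28 (3 and 6 adjusted over the list alone) and a median of -0.56, with Hist1h2bc at 1.25 ± 0.12. The list of translation initiation factors had 2 higher and 5 lower of 56 (3 and 7 adjusted over the list alone). Eif2ak3, a stress kinase gene that the list took in by its symbol, was at -1.55 ± 0.20. The decay factor gene Lsm14b changed by -1.03 ± 0.11 and the immediate early gene Maff by 2.79 ± 0.52. Zygotic genome activation genes had a median of 1.26 and 1 higher of 5 (4 adjusted over the list alone), which was Dub1a, not called without Trim21_3h replicate 3 (3.56, adjusted p = 0.0623; 9.71e-04 to 0.0623 over all alternatives). The 12 genes of the zona list had a median of 0.06.

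**Figure D5:**
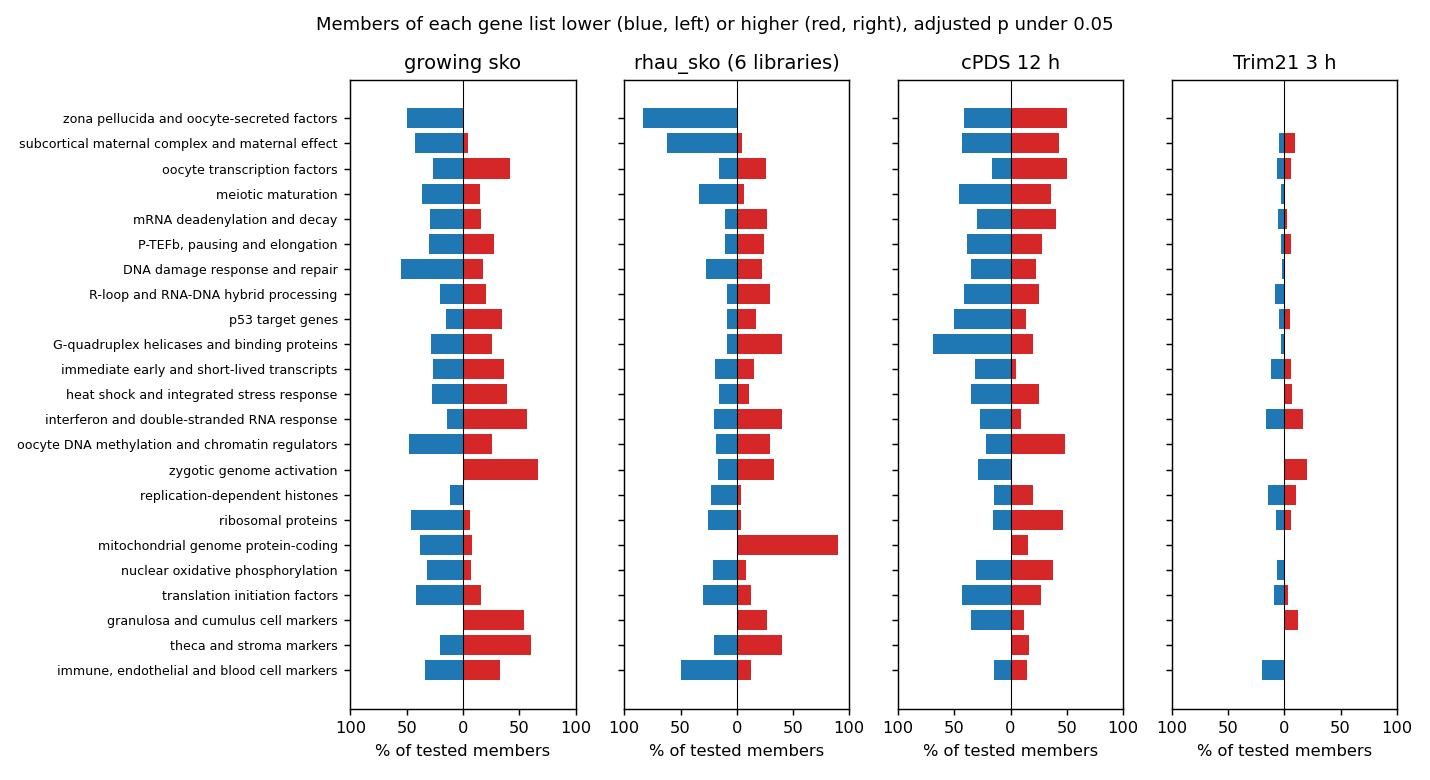
Percent of tested members called lower and higher in the 23 gene lists, 1 panel for each of growing sko, the 6 deep libraries of the DRB experiment, cPDS and Trim21. Ribosomal protein genes have 37 of 80 members lower in growing sko oocytes and 38 of 82 higher after cPDS.

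Across experiments, fold changes after cPDS or in the Trim21 libraries were weakly correlated with those of sko oocytes, and their calls overlapped in both directions. Pearson's r across genes was 0.15 between the 6 deep libraries and cPDS, and 0.11 between growing oocytes and cPDS. For the former pair 980 genes were higher in both (711 expected of independent lists) and 1106 lower in both (811 expected), with 579 and 653 called opposite ways (825 and 699 expected). For growing oocytes and cPDS these were 1104 (998 expected) and 1367 (1079 expected), while 855 were higher in sko and lower after cPDS (1153 expected) and 984 the other way round (934 expected). It was 0.072 between the deep libraries and Trim21, with 280 higher in both (167 expected), 198 lower in both (140 expected), 157 higher in sko and lower with Trim21 (132 expected) and 151 the other way round (176 expected), and 0.13 between growing oocytes and Trim21, the latter with 377 genes higher in both (224 expected) and 234 lower in both (176 expected) against 171 and 162 opposite (172 and 229 expected). For cPDS against Trim21 it was 0.017, with 310 genes higher in both (230 expected of independent lists) and 175 lower in both (209 expected), and 210 and 246 opposite (180 and 266 expected). DRB in c against DRB in sko gave -0.042, with a Spearman's rho of opposite sign at 0.078. Pabpn1l, Zar1 and Folr4 were lower both in growing sko oocytes and after cPDS, whereas Dhx36 fell in sko oocytes and rose after cPDS.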

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

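Except for the splits of the libraries and the test of the G-quadruplex list against random lists, the tests in this part were chosen only after the result was seen.

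The change between sko and control differed between growing oocytes and the DRB experiment for 2196 of 16655 genes (edgeR on 12 libraries, the 6 deep ones for the DRB experiment, with a term for the difference), 1321 more positive and 875 more negative in growing oocytes. Cdk9 differed by 1.74, Zp3 by 0.54 and Gdf9 by 0.68 on the log2 scale, each more positive in growing oocytes. Of 93 named genes 40 differed, among them Mt1 (3.51), Fshr (2.42), Btg2 (2.67, which changed by 2.39 in growing oocytes and by -0.26 in the deep libraries), Ddx6 (-1.48) and Tuba3b (-3.48). Most named genes were chosen by their change or p in these same experiments, so their share is no guide to all genes (13.2%). Dhx36 did not pass at 0.74 (edgeR adjusted p = 0.115). Of 3952 genes called in both experiments 3761 changed the same way, and 190 genes were called with opposite signs and a difference. Of 100 fitted splits, the real one included, 5 called at least the real 2196 genes, and the highest other count was 8947. The first 100 drawn held 87 that could be fitted, 4 of them with a count that high, and a further draw made up the 100. The 4 other splits with counts that high kept the growing groups whole and exchanged libraries of the other experiment, so their difference term still held the growing change, and the highest had the genotypes of the other experiment reversed. The 5 of 100 is therefore no measure of chance, which these splits could neither exclude nor favour.

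Other splits of the 6 libraries were fitted for the remaining counts, and 10 splits are too few for a share under 0.05. The real split called 7566 genes in growing oocytes, 6020 in the 6 deep libraries, 8191 for cPDS and 1630 for Trim21, and in each case the real split alone (1 of 10) reached its count and the highest other split called 0.

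The 2 shallow libraries of the DRB experiment carried 5.92% and 9.41% of counts on mitochondrial genes. Low depth alone was argued against, since deep libraries thinned to that depth reached at most 0.694%. DRB or the sko genotype itself was argued against, since the 6 deep libraries, which cover all 4 groups, reached at most 0.633%. Genes without a count in 12 growing and GV libraries took a share at least 17.6 times that of any deep library of the experiment, which is consistent with reads from genomic DNA, nuclear and mitochondrial. A wrong label or mixed sample stays open for the library labelled rhau_sko replicate 6. Its Dhx36 level of 46.9 CPM, from 6 counts, runs against the label, while its Mt1 level of 326 normalised CPM from 47 counts lies between those of c (6.09 and 7.44 CPM) and rhau_sko replicate 5 (859 CPM). With this library as the only sko one without DRB, the median log2 fold change of all genes was -2.56, against -0.05 with all libraries. Negative values in that fit cannot be told apart from this shift and do not bear on the label. They include Ubash3b (-3.17), which kept the sko direction, and 6 named genes that turned against it. Those 6 were Obox3 (-5.54), Plk2 (-8.35), Ddit4 (-0.29), Dub1a (-7.85), Ndufa4l2 (-7.66) and Dcn (-8.38). Ddx6 kept the sko direction against the shift, at 2.22.

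Between the Trim21 and Trim control libraries, 128 called genes with matched exons differed at least 4-fold. Trim21 and genes of low mean abundance were left out of this number. A response of the Trim21 libraries as the main source was argued against, because for only 14.8% of them (19 of 128; 95% interval 9.18 to 22.2) were the controls nearer than the Trim21 libraries to GV_C. With c or growing controls as the reference this share was 28.1% and 31.2%. Oocytes of the sko line in the Trim21 libraries were tested on 1349 genes, with Dhx36 left out. These genes were called and changed at least 2-fold the same way in both sko experiments. That source was argued against for them, since they moved there by a median of 0.0864 of their sko change (quartiles -0.132 to 0.306). Of these genes, 162 were called there in their sko direction and 74 against it, so a lean towards the sko change remained. Dhx36 itself went the way of the sko line, at 7.74 CPM with Trim21 against 30.4 CPM in the Trim controls. A response of the control libraries, or oocytes of another mouse background in them, may underlie the genes that set the controls apart, and neither was tested.

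After cPDS, the list of G-quadruplex helicases and binding proteins had a median of -0.55, and all of 10000 random lists matched on abundance and exon length lay above it (percentile 0; their central 95% ran from -0.26 to 0.24), which argues against abundance and length as the source. A steady trend with transcript length over all genes was also argued against, since the median of the fifth of genes with the longest transcripts minus that of the shortest was -0.0810. Over 5 equal groups of genes from short to long transcripts the medians were 0.14, -0.080, -0.072, -0.047 and 0.058, and 17.6% of genes were lower in the shortest against 31.7% and 33.4% in the following 2, so a dependence on length that is not steady remains. The fall may reflect a response to the ligand or the time in culture, which the labels do not separate. No GC correction was run.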

How the results depend on the processing

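Fits without the 2 shallow libraries and of the 6 deep libraries were chosen only after the data were seen.

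For growing oocytes the count of 7566 called genes was within 1.5 times under every alternative but the stricter filter, which tests fewer genes and gave 4884, and leaving out 1 library gave 6625 to 7687. For cPDS (8191) no alternative moved the count by 1.5 times, and leaving out 1 library gave 7012 to 8066. For Trim21 (1630) leaving out 1 library gave 928 to 1936, lowest without Trim21_3h replicate 3, and 1043 without Trim21_3h replicate 1; fewer samples were fitted there, and no other alternative moved the count by 1.5 times. With the replicate number as a block, cPDS gave 7559 genes and Trim21 1762. Deviations of same-numbered libraries correlated at -0.24, -0.32 and -0.19 for cPDS and at 0.43, 0.37 and -0.29 for Trim21. Not every library correlated best with its own number. So few libraries per group cannot exclude a pairing by number, and for Trim21 the values went both ways.

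The DRB experiment depended most on the processing. For sko without DRB (1706) DESeq2 called 256, limma-voom 4182, the fit without the shallow libraries 3775 and the 6 deep libraries 6020, and leaving out 1 library gave 104 to 2310. For sko with DRB (1724) these were 323, 4476, 4070 and 6020, and leaving out 1 library gave 0 to 1676. For DRB in c (4) no filter gave 1, the stricter filter 10, limma-voom 10, removal of mitochondrial genes 7, the 4 libraries alone 230, the fit without the shallow libraries 7 and the 6 deep libraries 2, and leaving out 1 library gave 0 to 1. For DRB in sko (3) no filter gave 0 (edgeR, 1562 genes at unadjusted p under 0.05), the stricter filter 13, limma-voom 5, the 4 libraries alone 116 and the fit without the shallow libraries 6, and leaving out 1 library gave 0 to 21. For the interaction (0; edgeR, 937 genes at unadjusted p under 0.05) the stricter filter gave 17, DESeq2 5, limma-voom 3 and the fit without the shallow libraries 6, and leaving out 1 library gave 0 to 10. Where a setting fits fewer libraries or tests fewer genes its construction enters, and otherwise the cause was not tested.

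Among the named genes that were called, changes of sign were seen in that experiment alone, and signs of the other called genes were not compared. For sko without DRB, leaving out 1 library took Obox3 from -5.54 to 3.36, Plk2 from -8.35 to 2.67, Ddit4 from -0.29 to 1.53, Dub1a from -7.85 to 5.76, Ndufa4l2 from -7.66 to 2.66 and Dcn from -8.38 to 1.77. Each was lowest without rhau_sko replicate 5, which leaves the library labelled rhau_sko replicate 6 alone in its group. The median of all genes was -2.56 in that fit, against -0.05 with all libraries, so these turns cannot be told apart from that shift. For sko with DRB, leaving out 1 library took Klf4 from -2.44 to 7.87, Hist3h2ba from -2.64 to 7.90 and Kdr from -7.74 to 3.90. Each was highest without c_DRB replicate 3, which leaves a shallow library alone. The median of all genes was 5.13 in that fit, against 0.06 with all libraries, so these turns cannot be told apart from that shift either. For DRB in sko, leaving out 1 library took Dub1a from -5.21 to 8.40, highest without rhau_sko replicate 5, where the median of all genes was 3.62. A lone library is assumed there to vary like the other groups. DESeq2 gave 0.27 for Hist1h1b without DRB and -0.30 for mt-Atp8 with DRB, and the cause was not tested.

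Among named genes, growing oocytes kept direction and call in 394 of 395 values under other settings and 346 of 348 with a library left out, cPDS in 461 of 465 and 338 of 354 (5 genes lost a call), and Trim21 in 393 of 398 and 214 of 270 (15 genes lost a call). For sko without DRB it was 368 of 427 and 77 of 176.

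With an estimated correlation 0 gene lists passed camera, against the preset's 1 for growing oocytes, 5 and 3 for sko without and with DRB, 7 and 5 for DRB in c and in sko, 6 for the interaction, 2 for cPDS and 2 for Trim21. That setting also uses the few residual degrees of freedom of each fit, so these failures do not single out the correlation between genes. Over genes of log2 CPM of at least 4, the Pearson correlation of sko with Trim21 moved from 0.0669 to 0.0249. That of DRB in c with DRB in sko moved from -0.042 to -0.27, and the cause of either move was not tested. Spearman's rho of the DRB pair was positive, at 0.078 over all genes and 0.16 over these, so no direction was settled. A shallow library was on the DRB side in c and on the side without DRB in sko. The test of G-quadruplex motifs and the correction for GC content, planned together with length, were not run, as no genome was used, and a correction for length alone was not run either. Depth limited the shallow libraries, where 4 to 6 counts stood behind Dhx36.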

Other observations

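Tests in this part were chosen only after results were seen.

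Dhx36 lies on chromosome 3, and genes within 10 Mb of it were compared with the rest for changes of at least 2-fold. In growing oocytes 21 of 64 genes in that window (32.8%) were called against 27.7% elsewhere, in the 6 deep libraries 14 of 70 (20%) against 18.9%, and in both 8 of 64 (12.5%) against 11.7%. Fisher's exact test, two-sided, gave an adjusted p of 0.845 for each of 3 tests, so no excess near the gene was detectable.

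The 6 deep libraries of the DRB experiment differed in mitochondrial share by group, with 0.126% and 0.134% in the c libraries, 0.170% in c_DRB replicate 3, 0.302% in rhau_sko replicate 5, and 0.397% and 0.633% in the rhau_sko_DRB libraries. Growing oocytes carried 0.796% to 1.08% in both genotypes. Replicates of a group differed by more than counting error in every pair, with a chi-squared per degree of freedom of 6.83 to 71.7, so no pair was a copy of the same reads.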
